A study of Rattus norvegicus with 4 samples.

How the data were processed

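YY1-bound DNA was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in skin of male Sprague-Dawley rats, an outbred laboratory stock. The labels give an age of 4 weeks for every library. YY1 is a zinc-finger transcription factor that activates some genes and represses others. The series holds 4 libraries: 1 YY1 ChIP library and 1 input library (sheared chromatin sequenced without immunoprecipitation) from skin given 45 Gy of electron-beam radiation, and 1 of each from a nonirradiated skin area. Groups were taken from the tissue source named in the labels. The library titles use the prefixes NC for the irradiated and Norm for the nonirradiated skin, which the labels do not define, and the tissue source is the field relied on here. If NC marks a control sample of another kind, the values given as irradiated would not describe irradiated skin, and every comparison between the areas would need another reading. The time between irradiation and sampling, the number of animals per library and any sharing of animals between the skin areas are not given in the sources used here.

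Per the labels' protocols, DNA was recovered with a commercial YY1 antibody, made into libraries with an NEBNext kit and read as 150-base paired ends on an Illumina HiSeq. The submitters' processing notes list cutadapt 1.9.1, a read trimmer, Bowtie2 2.2.4, an aligner, and the rat genome build rn5. The deposited values are 2 peak lists, 1 per ChIP library, in which each peak has a position, a width and a score. The peak identifiers name the peak caller MACS, whose version is not given in the sources used here. That the input of the same area served as control is taken from the names of the deposited lists and was not tested. The deposited score behaves as −10 log10 of the peak's p-value: its lowest value was 50.01 in the irradiated list and 50 in the nonirradiated list, which corresponds to a p threshold of 1e-05. The score is the authors' own value for each peak, it grows with sequencing depth as well as with enrichment, and it was used to rank, filter or describe peaks within a list. Where scores or score minimums of both lists stand side by side, they are the deposited values, which were not brought to a common scale. Each list was called on 1 library, with no pooling recorded. Duplicate handling, mapping filters and read totals are not given in the sources used here, so the depth behind each peak is unknown.

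Positions are given on rn5, 1-based. No rn5 sequence or gene annotation was used here. The only gene table at hand is for the GRCr8 assembly, and on 13 of the 21 chromosomes the last peak lies beyond that table's last gene. On chromosome 4 the last peak ends at 248249437, against a last gene end of 184404305. Peaks were therefore not assigned to genes, and the planned comparisons of promoters, gene classes, cell type markers, the YY1 motif and the Yy1 gene itself were not run. Regions are named by the rule set for that case before the data were examined: the 5 highest-scoring peaks that overlap between the lists (ranked by the lower of their 2 scores), the 5 highest found only in the irradiated list and the 5 highest found only in the nonirradiated list. Ties went to the wider peak, taken over both peaks for a shared pair.

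Peaks of the 2 lists were called overlapping when they shared at least 1 base. The chance level came from 100 random placements of the other list's peaks on their own chromosomes, with their widths kept and each chromosome taken to end at the last peak of either list. A second chance level, added after the overlap had been seen, moved the whole irradiated list by 10 to 500 kb in steps of 10 kb in both directions, which keeps regional density. Shares carry Wilson 95% intervals, which cover counting error only. A count of 0 was taken to allow up to 3 counts. Peak density was counted per Mb and in complete 1 Mb windows by peak midpoint, so that peaks in the incomplete last window of a chromosome are left out of window counts. The density over windows with a peak divides all peaks of a chromosome by its complete windows that hold a peak. With 1 ChIP library per skin area, no difference between the areas has a replicate check, no p-value was computed between them, and no fit with a batch term can be made. Alternatives were a score of at least 100, assembled chromosomes only, lists of equal length, removal of the widest 5% of peaks and other definitions of overlap. Score minimums of 200 and 300 and the use of windows with a peak were added after the data had been seen. The overlap routine, tested on simulated data, recovered 500 of 500 planted shared peaks among 9502 and returned the same counts as bedtools 2.31.1 (549 with the 1-base rule, 408 with reciprocal 50% overlap). The fit of a background mean to the scores, used in the closing section, recovered planted means of 1.3 and 2.2 as 1.3 and 2.2001. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.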

Results

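The series holds YY1 ChIP-seq of rat skin given a dose of 45 Gy and of a nonirradiated skin area. Each area gave 1 ChIP library and 1 input library, and the names of the deposited peak lists set each ChIP library against the input of its own area. The areas are those of the tissue source in the labels, and every comparison below depends on that reading, since the title prefix NC of the irradiated libraries is undefined. The irradiated list held 16934 peaks and the nonirradiated list 9502, a ratio of 1.78. All peaks lay on the 20 autosomes and the X chromosome. The irradiated peaks covered 7.94 Mb and the nonirradiated peaks 5.37 Mb. There were no replicate libraries for any value below, and read totals were not known, so the number of peaks cannot be set against depth.

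The irradiated list was longer, while the highest deposited scores were in the nonirradiated list. The score depends on depth, which is unknown, so scores of the 2 lists are not on a common scale and do not rank binding strength between the skin areas. Irradiated peaks had a median score of 68.5 and a median width of 480 bases. Nonirradiated peaks had a median score of 60.7 and a median width of 536 bases. Many peaks were close to the calling threshold of 50, with 26.4% of irradiated and 47.8% of nonirradiated peaks scoring under 60. At a score of 100 or more, 2819 irradiated peaks (16.6%, Wilson 95% interval 16.1 to 17.2) and 677 nonirradiated peaks (7.12%, 6.62 to 7.66) remained, a ratio of 4.16. At 200 or more the numbers were 111 and 108. At 300 or more the order turned, with 6 irradiated peaks (0.0354%, 0.0162 to 0.0773) and 77 nonirradiated peaks (0.810%, 0.649 to 1.01). No irradiated peak reached 500, a score that 53 nonirradiated peaks reached or passed, and 27 of these reached 1000. The highest score was 431.38 in irradiated and 3206.1 in nonirradiated skin. Which skin area held more peaks thus depended on the score minimum.

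**Figure D1:**
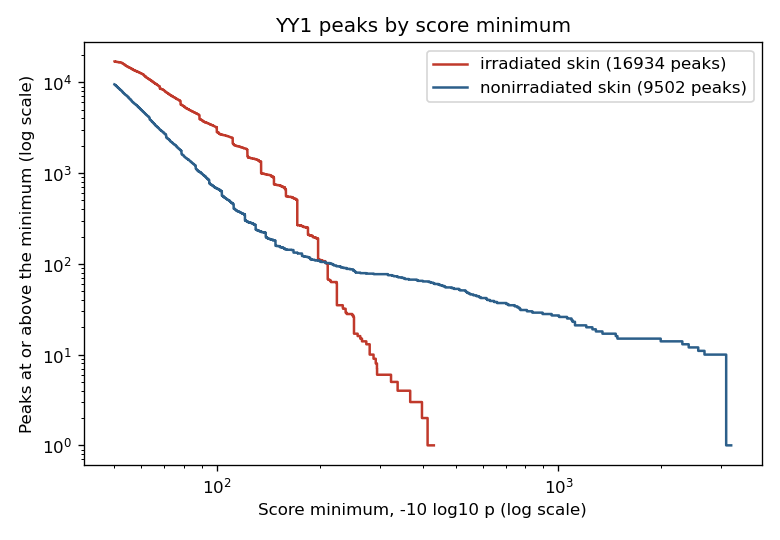
Number of YY1 peaks (y axis, log scale) whose deposited score (−10 log10 p) is at or above the value on the x axis (log scale), with 1 line per skin area. The irradiated line is the higher one at a score of 100 (2819 against 677), the lines meet near 200 (111 and 108), and the nonirradiated line is the higher one at 300 (77 against 6). The scores were not brought to a common scale.

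The next comparison asked which YY1 sites were common to irradiated and nonirradiated skin. Very few peak positions were shared. Of the 16934 irradiated peaks, 92 overlapped a nonirradiated peak (0.543%, Wilson 95% interval 0.443 to 0.666). The same 92 pairs made up 0.968% of the 9502 nonirradiated peaks (0.790 to 1.19). The remaining 16842 irradiated and 9410 nonirradiated peaks had no counterpart in the other list. Random placement of the irradiated peaks gave 57.6 ± 7.77 overlapping nonirradiated peaks (mean ± SD over 100 placements) and at most 75, so the observed number was 1.60 times the chance level. Moving the irradiated list as a whole along the chromosomes gave 63.3 ± 8.16 (SD over 100 moves) and at most 83. The observed number was 1.45 times the mean of these moves. The excess over these moves was 28.8 peaks, or 0.303% of the nonirradiated list. Allowing a distance of up to 1 kb raised the number to 265 nonirradiated peaks (2.79%), against 171 ± 12.3 at random.

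**Figure D2:**
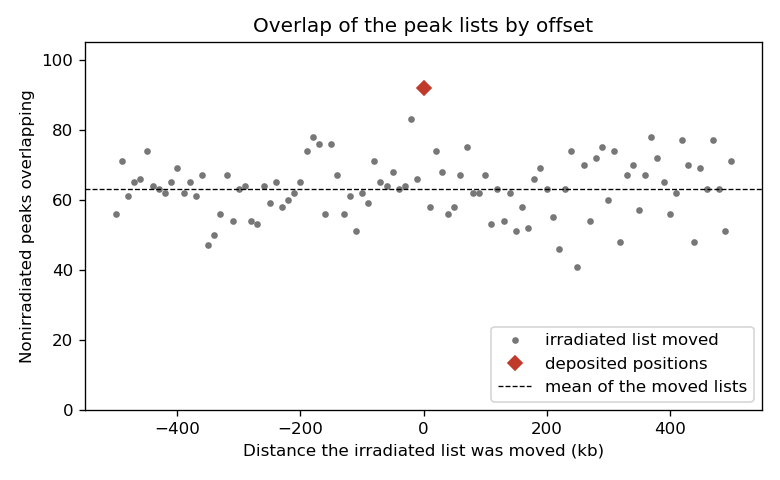
Number of nonirradiated peaks that overlap an irradiated peak (y axis) when the irradiated list is moved along the chromosomes by the distance on the x axis (kb). Grey points are the 100 moved lists, the dashed line is their mean of 63.3, and the diamond is the 92 overlaps at the deposited positions, above the highest moved list at 83.

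Overlap was not concentrated among the higher-scoring peaks. In the irradiated list, 20 of the 4234 peaks in the top 25% by score overlapped a nonirradiated peak (0.472%, 0.306 to 0.729), against 31 of 4234 in the bottom 25% (0.732%, 0.516 to 1.04). In the nonirradiated list the top 25% had 28 of 2376 (1.18%, 0.817 to 1.70) and the bottom 25% had 24 of 2376 (1.01%, 0.680 to 1.499). These intervals overlapped within each list. None of the 111 irradiated peaks with a score of at least 200 overlapped any nonirradiated peak, which allows a share of up to 2.70%. None of the 108 nonirradiated peaks of that score overlapped an irradiated peak, which allows up to 2.78%. Both limits lie above the shares of the whole lists (0.543% and 0.968%), so these counts of 0 do not show a lower overlap. No pair scored 100 or more in both lists, where only 0.57 overlaps were expected at random. Peak width also varied with score, and no chance level was computed for the score groups.

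The shared peak pairs with the highest scores lay on chromosomes 3, 7, 8 and 4. The first, at chromosome 3:171348597-171348949 in irradiated skin, had a score of 99.77 there and 133.67 in nonirradiated skin, where it spanned 171348577-171348999. On chromosome 7, the irradiated peak at 2081899-2082595 scored 98.13 and its nonirradiated counterpart at 2081134-2082404 scored 84.62. Chromosome 8 held a pair at 120512451-120512750 (score 111.07, irradiated) and 120512230-120512636 (77.53, nonirradiated). Another pair on chromosome 8, at 20338716-20339052 (78.14, irradiated) and 20338253-20338719 (83.97, nonirradiated), shared only 4 bases. The fifth pair, at chromosome 4:191633448-191633961 (76.9, irradiated) and 191633223-191633543 (91.6, nonirradiated), shared 96 bases. Over all 92 pairs the median score was 66.1 in irradiated and 63.0 in nonirradiated skin. Genes at these positions were not analysed here.

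Peaks found only in irradiated skin were led by short regions on chromosomes 5, X, 3 and 4. The highest score, 431.38, was at chromosome 5:85746581-85746780, a peak of 200 bases that lay 12.3 kb from the nearest nonirradiated peak. Peaks on the X chromosome at 120082820-120083069 and 100088053-100088350 scored 413.55 and 367.76. The peak at chromosome 3:74283029-74283283 scored 398.16, and the one at chromosome 4:23075605-23075804 scored 337.88. The nearest nonirradiated peak to these 4 was between 43.1 kb (chromosome 3) and 745 kb (chromosome 4) away. The 111 irradiated peaks with a score of at least 200 had a median width of 255 bases, against 480 for the whole list. The narrowest peaks of the list spanned 200 bases. Many of the 111 scores were tied, for example at 251.7, 224.27 and 210.82, so the score does not order those peaks among themselves. On the X chromosome lay 9 of the 111 (8.11%, Wilson 95% interval 4.32 to 14.7), against 2.02% (1.82 to 2.24) of all irradiated peaks. This was not particular to irradiated skin. Of the 108 nonirradiated peaks with a score of at least 200, 6 lay on X (5.56%, 2.57 to 11.6), against 1.94% (1.68 to 2.23) of all nonirradiated peaks.

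Peaks found only in nonirradiated skin had deposited scores of up to 3206.1, on a scale that depends on the depth of that library. This highest score was at chromosome 2:218529729-218530463, where the nearest irradiated peak was 20.6 kb away. Another 9 peaks had the identical score of 3100, so the score does not order these 9 among themselves. Such a tie may mark a ceiling of the score, in which case the peak at 3206.1 cannot be ranked above the 9 either. The widest of the 9 were at chromosome 15:81667735-81669024 (1290 bases), chromosome 7:116205589-116206609 (1021 bases), chromosome 4:246164280-246165205 (926 bases) and chromosome 15:31738452-31739359 (908 bases). The nearest irradiated peaks to these 4 lay 33.8 to 275 kb away. The 77 nonirradiated peaks with a score of at least 300 were spread over 17 chromosomes, with a median width of 671 bases. Of the 77, 2 had an irradiated peak within 1 kb (2.60%), against 2.79% of the whole nonirradiated list. The absence of a peak from a list does not show that YY1 was absent there, since read coverage at these positions was not analysed here.

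Peaks of both skin areas were spread over all chromosomes, with the fewest per Mb on the X chromosome. Chromosome 1 held 10.6% of irradiated peaks (10.2 to 11.1) and 11.2% of nonirradiated peaks (10.6 to 11.8). Chromosome 3 held 6.70% (6.34 to 7.09) and 5.99% (5.53 to 6.48), and chromosome 16 held 3.47% (3.20 to 3.75) and 2.94% (2.62 to 3.30). The intervals of the 2 lists overlapped on all 21 chromosomes, which is not a test of the differences, and these were not tested. Autosomal density ranged from 4.66 (chromosome 4) to 6.53 (chromosome 16) peaks per Mb in irradiated skin and from 2.75 (chromosome 4) to 3.73 (chromosome 8) in nonirradiated skin. The low value of chromosome 4 goes with a stretch of 65.3 Mb, from 67943574 to 133248702, that held no peak of either list. The X chromosome had 2.22 irradiated and 1.19 nonirradiated peaks per Mb. Relative to the autosomes this was 0.367 (0.329 to 0.408) in irradiated and 0.351 (0.304 to 0.406) in nonirradiated skin. At a score of 100 or more the ratio was 0.654 and 0.541, given without an interval.

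**Figure D3:**
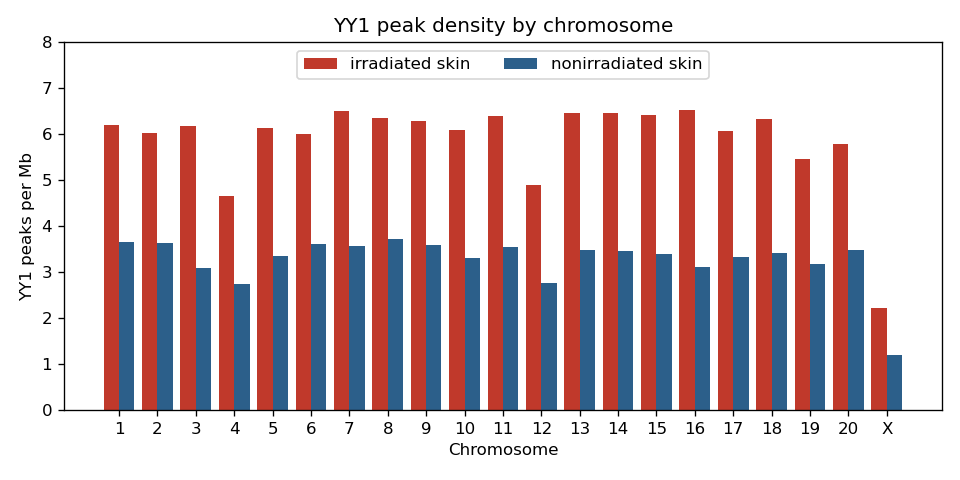
YY1 peaks per Mb (y axis) on each chromosome (x axis) in irradiated and nonirradiated skin, with 1 bar per list and no error bars because there is 1 library per skin area. Both lists are lowest on the X chromosome, at 2.22 and 1.19 peaks per Mb.

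Peak numbers of the 2 lists were also compared in windows of 1 Mb. Over the 2604 autosomal windows that held a peak of either list, the correlation of the peak numbers was 0.0469 (Pearson) and 0.0458 (Spearman). With the X chromosome included, over 2750 windows, it was 0.129 and 0.134. Windows without a peak of either list were left out. With a mean of 6.13 irradiated and 3.44 nonirradiated peaks per window, counting error alone lowers such a correlation, and the highest value it allows was not computed, so these values do not show how alike the regional densities were. Windows along the genome are not independent replicates, and no p-value is given. The irradiated list was densest on chromosome 3 between 126 and 127 Mb, with 19 peaks against 5 nonirradiated peaks. Windows on chromosome 7 (90 to 91 Mb) and chromosome 11 (18 to 19 Mb) followed with 17 irradiated peaks each, against 1 and 4 nonirradiated peaks. Nonirradiated peaks were densest on chromosome 2 between 1 and 2 Mb and on chromosome 19 between 38 and 39 Mb, with 15 peaks each against 7 and 4 irradiated peaks. These windows were chosen after their values had been seen. In 100 random placements the densest window held a mean of 16.65 and at most 20 irradiated peaks, and a mean of 11.69 and at most 16 nonirradiated peaks, so the observed maxima lay above the random means and below the random maxima. Over all 2891 complete windows, the variance of the peak number divided by its mean was 1.58 in irradiated and 1.38 in nonirradiated skin, against 1.16 and 1.09 at random. The random placements did not keep empty the 141 windows that held no peak of either list.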

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

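With 1 ChIP library per skin area, no library could be left out. Of 44 alternative values, 21 stayed close to the reported one, 21 moved and 2 changed direction. Those that stayed close include every value for assembled chromosomes only, and the nonirradiated relative density on X at equal list length. These could not change, because the peaks used were identical. Among those that moved, peak numbers at higher score minimums could not rise. Shares of overlapping peaks could not rise under the stricter overlap rules and could not fall within 1 kb. The direction of these moves was fixed in advance, so they do not measure how stable the results are. At a score of at least 100 the lists held 2819 irradiated and 677 nonirradiated peaks (ratio 4.16), and the overlap fell from 92 to 0, giving 0% of both lists and 0 times the chance level. Only 0.57 overlaps were expected at random there, so this value has too few peaks to carry a direction. Score minimums added after seeing the data left 111 and 108 peaks (ratio 1.03) at 200 and 6 and 77 peaks (ratio 0.0779) at 300, which reverses the order of the skin areas. Tests of the high scores, under the other observations, left the cause open. When 50% of the shorter peak had to be shared, 0.348% of the irradiated and 0.621% of the nonirradiated list overlapped (1.75 times chance). Reciprocal overlap of 50% gave 0.272% and 0.484% (2.19 times chance). A distance within 1 kb gave 1.55% and 2.79% (1.55 times chance). Without the widest 5% of peaks the overlap was 1.46 times chance. With both lists limited to 9502 peaks, 0.474% of the nonirradiated list overlapped (1.40 times chance). Relative density on the X chromosome was 0.654 (irradiated) and 0.541 (nonirradiated) at a score of at least 100, and 0.425 in the irradiated list at equal length. These alternative ratios are given without an interval. Every peak lay on an assembled chromosome, so that setting moved nothing. Unknown read depth limits what the absence of a peak shows.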

Other observations

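Apart from the score minimum of 100, which was planned, the tests in this part were chosen after the results they bear on had been seen.

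The peak lists of irradiated and nonirradiated skin shared 92 positions. A mismatch of genome builds between the lists would give such a result, but 8 of the 10 longest peak-free stretches of the irradiated list lay at the same place in the nonirradiated list, agreeing over at least 90% of their length, and the overlap was highest at the deposited positions. Sites common to both areas but missed at the threshold when weak would be expected to leave the strong peaks shared. The upper 95% limit of the overlapping share among the top 25% of peaks by score was 1.70% (the higher of the lists). This does not exclude missed common sites. Scores of the lists are not on 1 scale, so a high score in 1 list does not ensure a call in the other. Of the 100 moved lists, 0 gave as many overlaps, and the excess over their mean was only 0.303% of the nonirradiated peaks. Placed or moved peaks could fall in stretches where no peak can be called, which would make the chance level too low. Chance coincidence as the whole of the overlap is therefore not excluded. The peaks without a counterpart may reflect YY1 binding that differs between irradiated and nonirradiated skin, or common sites missed in 1 library. They may also include peaks that would not recur in a second library of the same skin. These cannot be told apart with 1 ChIP library per area. A test would need 2 or more ChIP libraries of each area.

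The nonirradiated list has a tail of 77 peaks with a score of at least 300, against 6 in the irradiated list. Scores in both lists repeat on fixed steps, as tail probabilities of a Poisson count do when a peak is judged against a library-wide background. The steps fit a background mean of 1.04 for 3258 irradiated scores (19.2% of those under 300) and of 2.91 for 896 nonirradiated scores (9.51%), with a tolerance of 0.01, while the next best means fitted 732 and 235. If the caller worked that way, the background per scanned stretch was 2.79 times higher in the nonirradiated library, so that scores of the 2 lists are not on 1 scale. A difference in depth may therefore contribute to the tail. It stays open, because the background mean also depends on fragment length and read totals are unknown. Places where the assembly itself draws reads, such as collapsed repeats, may contribute too. Of the 77 peaks, 2 had an irradiated peak within 1 kb (2.60%), against 2.79% of the whole list. The irradiated input, if used as control, could have removed such places from the irradiated list. The nonirradiated input, if used likewise, could have removed them from the nonirradiated list too, so this stays open. A loss of YY1 from these sites after irradiation also stays open and was not tested.

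Peak density on the X chromosome was low in both lists. Whole 1 Mb windows without a peak of either list do not account for it, since over windows that held a peak the ratio to the autosomes was at most 0.368. Shorter stretches inside those windows were not removed, so an effect of the assembly is not excluded. A candidate explanation is the single X copy of male cells, which lowers the background on X. In line with it, 34.8% of irradiated X peaks (Wilson 95% interval 29.9 to 40.0) had scores on the library-wide background steps, against 18.9% (18.3 to 19.5) on the autosomes. In the nonirradiated list the shares were 13.0% (8.92 to 18.7) and 9.40% (8.83 to 10.01), whose intervals overlap. The median score on X was 76.9 in the irradiated list, against 68.3 on the autosomes. In the nonirradiated list it differed little (61.3 against 60.7). The rule for this explanation, written with these values known, also asked for a median score on X no higher than on the autosomes. The irradiated list did not meet that part. These medians do not decide the question, because a lower background on X would also raise the score of a given number of reads. At a score of at least 100 the relative density of X was 0.654 in the irradiated and 0.541 in the nonirradiated list. These ratios rest on fewer peaks and are given without an interval, so a rise was not tested. The X copy number therefore stays open, as does a lower density of YY1 sites on X, which was not tested.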
